A study of Mus musculus with 6 samples.

How the data were processed

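The series measured gene expression in liver of male mice on a Western diet by paired-end RNA sequencing, with 3 libraries of Prdx1 C52S mice and 3 of wild-type mice. Per the labels' protocols, total RNA was extracted with Trizol, samples with an RNA integrity number above 7.0 were used, and mRNA was selected from 5 µg of RNA with oligo(dT) beads in 2 rounds. Second strands were marked with dUTP and removed, adapters carried unique molecular identifiers, libraries were amplified in 8 PCR cycles to inserts of 300 ± 50 bp, and pairs of 150 nt reads were sequenced on a NovaSeq 6000. Poly(A) selection removes most transcripts without a tail, so that non-polyadenylated RNA is not measured here.

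The deposited table holds, for each of the 29734 genes and each library, an FPKM value and an estimated count, per the file headers. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR, with no role or order. FPKM values were deposited by the authors, per the file headers, scaled to transcript length and library depth,, and sum to between 367934 and 407756 per library. The deposited estimated counts are whole numbers proportional to FPKM times transcript length within a library, and their low values peak at 4 (6204 values, beside 3538 at 3 and 1965 at 5). They are estimates worth about 4 counts per fragment rather than tallies of reads, which count models then treat as more precise than they are at low levels. Whether reads were collapsed by molecular identifier, whether counting used the strand and how reads shared by paralogs were assigned are not given in the sources used here. The notes name the build mm9, but the gene coordinates are those of GRCm38. Of the 29734 identifiers, 29642 are in GENCODE release M21, and 26790 of these have the identical chromosome, start and end. Coordinates are therefore given on GRCm38. No row lacked a gene name, and 60 symbols stood on more than 1 row and were kept apart by identifier.

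Library totals were 75766562, 76164949 and 60326469 estimated counts in Prdx1 C52S 1, 2 and 4 and 72164981, 74725684 and 74446102 in WT 6, 8 and 9. At 4 counts per fragment, a total of 15.1 to 19 M fragments resolves most expressed genes, while a gene below about 0.1 FPKM rests on few fragments. TMM factors were 0.92, 0.883 and 0.901 in the Prdx1 C52S libraries and 1.04, 1.28 and 1.03 in the WT libraries. They raise the Prdx1 C52S values relative to WT, so that equal FPKM gives a positive log2 fold change. No libraries were identical, and each library's mean Pearson correlation with the other 5, over log2 CPM of all genes tested, was between 0.937 (WT 8) and 0.966.

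Estimated counts were rounded and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors, robust quasi-likelihood fits and F-tests, two-sided, with Benjamini-Hochberg adjustment over the 18931 genes that passed the filter and a threshold of 0.05. No covariate and no block was used. The common biological coefficient of variation was 0.31, and 0.245 without WT 8. Of 50 gene lists written from textbook knowledge before the data were examined, 48 had at least 5 tested members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Camera compares a list with all other genes, so its direction is relative to them. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were alternatives. With an estimated correlation, camera also uses the residual degrees of freedom of the 6 libraries, which are few. A list that is not called there is therefore weak evidence against a difference. Members of a list were in addition adjusted over the list alone. The correlations estimated here ran from -0.003 for the Toll-like receptor and NF-kB list, 0.016 for chemokines and cytokines and 0.021 for monocytes to 0.84 for the respiratory chain and 0.90 for cholangiocytes, so that the preset value lies below most but not all of them.

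The genes named in the text followed a rule written before the data were examined. It takes Prdx1; the 12 genes with the largest fold changes in each direction among those past adjusted p 0.05 with non-overlapping groups, a mean of at least 1 FPKM in the higher group and no predicted gene model, of which there were 0; the 4 members of each called list with the smallest p; at most 2 members of each list not called; and a panel of 10 genes (Tnf, Il1b, Ccl2, Adgre1, Cd68, Trem2, Clec4f, Col1a1, Timp1 and Acta2). Some genes that the rule names are not reported here. Genes outside this rule are named as chosen after their values were seen, and Krt19, Glul and Alb are named as values of WT 8 under the same condition. Of the 169 genes the rule names, 22 overlap another gene on the same strand and 35 a gene on the other strand, and reads of such pairs may not have been told apart. Globin, Mup, Cyp2a, Cyp2c, Ugt2b, Gstm and metallothionein genes have close paralogs.

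The procedure was tested on simulated data with negative binomial counts drawn from the means, trended dispersions and library sizes of the real libraries, with 200 changed genes. For the comparison of all 6 libraries, over 18931 genes, it called 39 of 100 genes changed 2-fold and 73 of 100 changed 4-fold, with 7 false calls, and camera called a simulated list of 40 genes raised 1.5-fold and 0 of 48 unchanged lists. For the comparison without WT 8, over 19337 genes, it called 53 and 77 of 100, with 8 false calls. The simulated genes vary independently, so that this does not test how correlated genes affect camera. Each simulated gene had the dispersion of the trend at its level, without the scatter of single genes around it. The recovered genes and false calls may therefore differ from those of the test on the real libraries.

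Alternatives were limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean of at least 0.5 FPKM, DESeq2 1.42.0, DESeq2 size factors in edgeR, quantile normalisation, no filter, a mean CPM of at least 1, fits without robust estimation, library quality weights with voom and leaving out each library in turn. Added after seeing the data were scaling by library totals only, counts divided by 4, DESeq2 without WT 8, a covariate of mean biliary expression, and camera with an estimated correlation and fry without WT 8. KEGG pathways as annotated in the table, with 15 to 300 tested genes, were tested with camera in the same way. Figures were drawn with matplotlib 3.10.9. All 6 libraries were used.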

Results

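RNA sequencing of poly(A)-selected liver RNA was carried out on 6 libraries from male mice that were fed a Western diet for 20 weeks from an age of 8 weeks. A Western diet is rich in fat and sugar and is used to produce steatohepatitis, that is, fat accumulation with inflammation of the liver. The Prdx1 C52S group (3 libraries, replicates 1, 2 and 4) carried a Prdx1 allele in which cysteine 52 is replaced by serine, and the WT group (3 libraries, replicates 6, 8 and 9) carried the wild-type gene. Peroxiredoxin 1 is a thiol peroxidase that reduces hydrogen peroxide, and cysteine 52 is the residue that its substrate oxidises. The estimated counts per library summed to 60326469 in Prdx1 C52S 4 and to between 72164981 and 76164949 in the other 5 libraries, for 29734 genes. One sequenced fragment is worth about 4 of these counts, so that the depth corresponds to between 15.1 and 19 M fragments per library. Levels below are FPKM given as mean ± SD of n = 3 libraries, and log2 fold changes are Prdx1 C52S minus WT from edgeR with TMM scaling, given with their SE where it is stated. This SE was derived from the test, as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic.

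The comparison addressed which liver transcripts differ between the genotypes after the same diet, and, from the title of the series, whether transcripts of inflammation are lower with the C52S allele. Gene groups of macrophages, T cells, antigen presentation, cytokine signalling, extracellular matrix and bile duct epithelium were lower in the Prdx1 C52S livers. Groups of NRF2 target genes, cytochrome P450 metabolism, fat and sterol synthesis, bile acid transport and mitochondrial respiration were higher. These calls came from camera with a preset correlation of 0.01, which called 35 of 48 gene lists, 16 higher and 19 lower. With a correlation estimated from these libraries it called 0 of them, with adjusted p-values from 0.24 to 0.72 for the 35 lists. This loss does not come from the size of the correlation alone. For the Toll-like receptor and NF-kB list the estimate was -0.003, below the preset value. Its camera adjusted p still rose from 4.51e-06 to 0.24. Among single genes, Itgam, the integrin alpha M chain of myeloid cells, was at 0.513 ± 0.0444 in Prdx1 C52S and 2.41 ± 0.435 in WT (log2 fold change -1.93), and the lipid droplet protein Pnpla3 was at 8.14 ± 2.65 and 1.51 ± 0.249 (log2 fold change 2.73). No single gene passed adjusted p 0.05 in the edgeR quasi-likelihood test with all 6 libraries (0 higher and 0 lower of 18931 tested, smallest adjusted p 0.0553), while 4983 genes had an unadjusted p under 0.05, 2176 higher and 2807 lower. DESeq2 called 1145 higher and 1698 lower on the same libraries, voom with library quality weights 1023 and 1006, and limma on log2(FPKM + 1) 55 and 194. With all 6 libraries no member of any list passed over all genes tested, while without WT 8 members of many lists did, among them 13 of 35 NRF2 targets and 10 of 25 fat synthesis genes. Therefore counts within lists below are those adjusted over the list alone. WT 8 differed from the other WT libraries in its biliary, Kupffer cell and pericentral transcripts, and without it the same test called 522 genes higher and 375 lower of 19337.

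Prdx1 itself had nearly the same FPKM in both groups, with 247 ± 12.2 in Prdx1 C52S and 246 ± 20.7 in WT. The single libraries lay at 261, 238 and 242 in Prdx1 C52S 1, 2 and 4, and at 236, 232 and 270 in WT 6, 8 and 9. After TMM scaling its log2 fold change was 0.28 (SE 0.18, edgeR adjusted p = 0.347), and it was -0.01 when only the library totals were used, -0.16 after quantile normalisation and 0.15 without WT 8. With TMM scaling and all libraries, each Prdx1 C52S library lay above each WT library. A substitution of one residue leaves the transcript in place, so this level does not check the genotype labels. The gene (ENSMUSG00000028691) lies on chromosome 4 from 116685544 to 116700822 on the plus strand of GRCm38. Codon 52, TGT in the reference, lies at 116691823 to 116691825 in exon 3 of the 6 exons of Prdx1-204 (exon 116691776 to 116691929), where the change is C52S.

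Macrophage transcripts were lower in the Prdx1 C52S livers. Of 24 general macrophage genes, 23 had negative fold changes and 17 were lower when adjusted over the list alone (0 over all genes tested), with a median log2 fold change of -0.64. Without WT 8, 24 were lower when adjusted over the list alone and 20 over all genes tested. The list was called by camera (adjusted p = 1.02e-10, and adjusted p = 0.42 with an estimated correlation). Lysozyme 2 (Lyz2) was at 118 ± 11.1 against 302 ± 21.6 FPKM (log2 fold change -1.06, SE 0.14), the Fc receptor gene Fcgr3 at 7.38 ± 0.853 against 18.2 ± 0.182 (-1.02, SE 0.13) and the pan-leukocyte gene Ptprc at 1.17 ± 0.0606 against 2.62 ± 0.452 (-0.86, SE 0.11). Together with Itgam, these 4 genes each had an edgeR adjusted p of 0.0553 and groups that did not overlap. Of the 18 genes of lipid-associated macrophages, which accumulate in the steatotic liver, 8 were lower when adjusted over the list alone (camera adjusted p = 6.45e-05, and adjusted p = 0.42 with an estimated correlation). They included Cd63 (log2 fold change -1.55), osteopontin, Spp1 (-2.03), Lpl (-0.54) and Itgax (-1.09), and 15 were lower on that scale without WT 8. Spp1 is also a biliary gene and stands in the cholangiocyte list. Of 9 monocyte genes, 4 were lower when adjusted over the list alone, namely Plac8 (-0.77), the chemokine receptor Ccr2 (-1.13), F13a1 (-1.23) and Vcan (-1.22), with a camera adjusted p = 0.00158 and an adjusted p = 0.40 with an estimated correlation.

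Among macrophage genes named in advance, Adgre1, which encodes F4/80, was at 9.23 ± 0.539 against 14.7 ± 3.76 FPKM (log2 fold change -0.41, SE 0.26, edgeR adjusted p = 0.341). Without WT 8 its log2 fold change was -0.67 (SE 0.09) with an edgeR adjusted p = 0.0144, and without WT 6 it was -0.24. Cd68 was at 18.7 ± 3.69 against 29.6 ± 3.93 (-0.39, SE 0.21, edgeR adjusted p = 0.27; -0.25 without Prdx1 C52S 2 or without WT 6), and Trem2, a receptor of lipid-associated macrophages, at 2.06 ± 0.525 against 4.96 ± 1.49 (-0.99, SE 0.29, edgeR adjusted p = 0.109). The resident Kupffer cell genes were not called (0 of 12 when adjusted over the list alone, camera adjusted p = 0.0942), and their median was 0.22 with all libraries and -0.18 without WT 8. Camera called this list higher without WT 6 (median 0.45, camera adjusted p = 0.019) and without WT 9 (median 0.54, camera adjusted p = 0.028). Clec4f, a lectin of resident Kupffer cells, lay at 37.5 ± 8.18 against 31.1 ± 24.7 (0.47, SE 0.91), with 2.56 in WT 8 beside 44.8 in WT 6 and 46 in WT 9. Its log2 fold change ran from -0.08 without WT 8 to 0.87 without WT 9. The Kupffer list members with the smallest p were Id3 (-0.46, and -0.30 without WT 8) and the iron exporter Slc40a1 (0.34, and 0.22 without WT 8). The list of complement components was not called either (direction lower, camera adjusted p = 0.764, against a median of 0.03), and 4 of its 25 genes were lower when adjusted over the list alone. These were the macrophage genes C1qa (-0.86), C3ar1 (-1.13), C1qb and C1qc, the last pair named after their values were seen. One gene of this list, Cfd, was higher (3.55, also named after its value was seen). Without WT 8 camera called the complement list lower (median -0.17, camera adjusted p = 0.0272, and adjusted p = 0.40 with an estimated correlation). On that scale 10 genes were then lower and 3 higher, C8g, Mbl2 and Masp1, named after their values were seen.

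**Figure D1:**
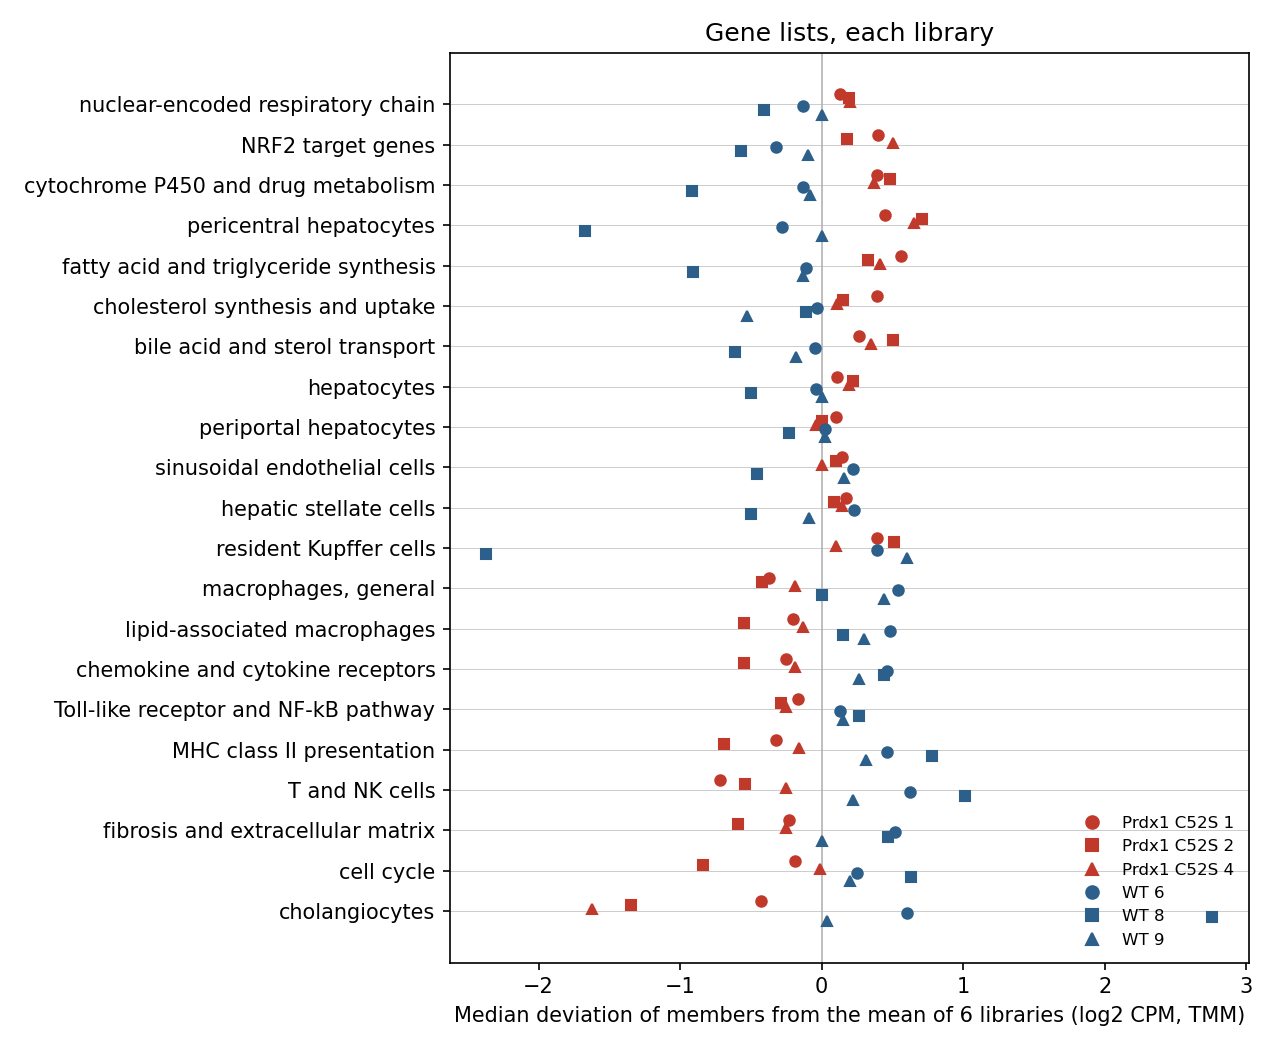
Median deviation of each list's members from their mean over the 6 libraries, in log2 CPM after TMM scaling (horizontal axis), for 21 of the gene lists (vertical axis), with 1 point per library (red, Prdx1 C52S; blue, WT). The macrophage list lies between -0.42 and -0.19 in the Prdx1 C52S libraries and between 0 and 0.54 in the WT libraries, and WT 8 stands apart at 2.76 for cholangiocytes and -2.37 for Kupffer cells.

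Signalling genes of inflammation were lower as well. Chemokine and cytokine receptors had 22 of 24 negative fold changes, and 15 were lower when adjusted over the list alone (camera adjusted p = 5.76e-09, and adjusted p = 0.40 with an estimated correlation). Examples were the interferon gamma receptor Ifngr1 (log2 fold change -1.12), Csf3r (-0.88) and Csf2ra (-0.68). In the Toll-like receptor and NF-kB list, 18 of 36 genes were lower when adjusted over the list alone and 1 was higher, Ikbkg (0.51, named after its value was seen). Its camera adjusted p was 4.51e-06 (adjusted p = 0.24 with an estimated correlation). Among them were the adhesion molecule Vcam1 (3.23 ± 0.493 against 10.3 ± 1.34, log2 fold change -1.37), the NF-kB inhibitor Tnfaip3 (-1.30), Traf1 (-1.35) and the lipopolysaccharide co-receptor Cd14 (-1.47). Of 32 chemokines and cytokines, 10 were lower and 1 was higher when adjusted over the list alone (camera adjusted p = 0.00125, and adjusted p = 0.40 with an estimated correlation). The lower genes included Il1rn (-0.95), Ccl9 (-0.46), Cxcl16 (-1.36) and Cxcl14 (-0.89). The higher one was Il18 (0.49), which also stands in the inflammasome list and passed in neither list without WT 8.

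The cytokine genes named in advance did not pass the test over all genes. Tnf was at 0.299 ± 0.0136 against 0.853 ± 0.366 FPKM (log2 fold change -1.18, SE 0.40, edgeR adjusted p = 0.131), with groups that did not overlap. Il1b was at 2.25 ± 1.06 against 3.25 ± 1.06 (-0.28, SE 0.41, edgeR adjusted p = 0.7), and its log2 fold change ran from -0.70 without Prdx1 C52S 1 to 0.07 without WT 9. Ccl2 was at 3.11 ± 0.277 against 5.9 ± 3.73 (-0.56, SE 0.34, edgeR adjusted p = 0.332), with 10.2 in WT 8, and its log2 fold change without that library was -0.08. Of 15 inflammasome genes, 3 were lower when adjusted over the list alone, Txnip (-1.19), Casp4 (-1.52) and P2rx7 (-0.54), and Il18 was higher (camera adjusted p = 0.00797, and adjusted p = 0.42 with an estimated correlation). The inflammasome median was -0.45 and was -0.25 without Prdx1 C52S 2, and 1 gene was lower on that scale without WT 8, Casp4 (-1 in that fit). Interferon response genes had a median of -0.21, and 7 of 48 were lower when adjusted over the list alone (camera adjusted p = 0.000209, and adjusted p = 0.51 with an estimated correlation). Oas1g (-1.01), Oasl2 (-1.03), Oas2 (-0.81) and Usp18 (-0.69) led this list, whose call was lost without Prdx1 C52S 1 (median -0.10, camera adjusted p = 0.091).

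**Figure D2:**
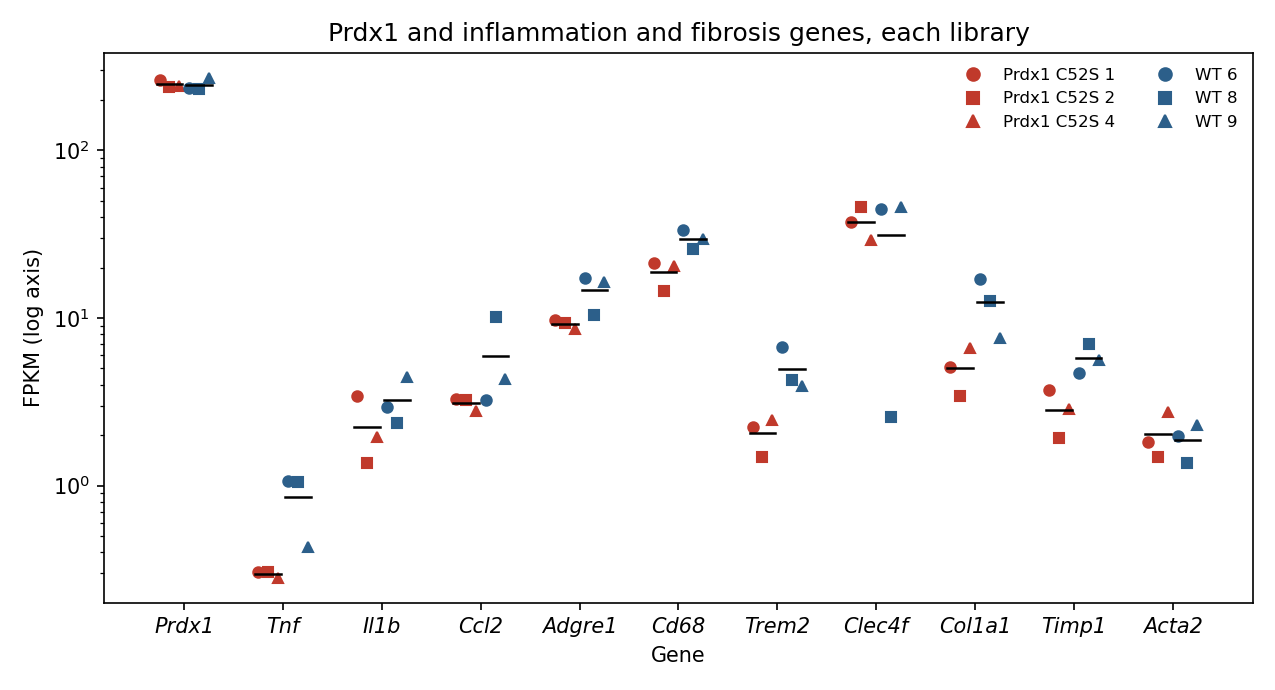
FPKM on a log axis (vertical) of Prdx1 and the 10 inflammation, macrophage and fibrosis genes named in advance (horizontal), with 1 point per library (red, Prdx1 C52S; blue, WT) and black lines at the group means. Prdx1 lies between 232 and 270 in the 6 libraries, the groups of Tnf, Adgre1, Cd68, Trem2, Col1a1 and Timp1 do not overlap in FPKM (those of Adgre1 and Cd68 overlap after TMM scaling), and Clec4f is at 2.56 in WT 8.

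Transcripts of T and NK cells and of antigen presentation followed the same direction. T and NK cell genes had a median log2 fold change of -1.19, and 13 of 34 were lower when adjusted over the list alone (camera adjusted p = 1.01e-07, and adjusted p = 0.42 with an estimated correlation). The co-receptor gene Cd8a was at 0.164 ± 0.0345 against 1.05 ± 0.42 FPKM (-2.31), the T cell receptor constant gene Trac at 0.321 ± 0.0224 against 1.77 ± 0.398 (-2.13) and Cd3e at -2.77 on the log2 scale. All 13 genes of MHC class II presentation had negative fold changes, and 9 were lower when adjusted over the list alone (camera adjusted p = 3.54e-06, and adjusted p = 0.41 with an estimated correlation). The invariant chain Cd74 was at 127 ± 35 against 325 ± 109 (-1.03), H2-Aa at -1.01, H2-Eb1 at -1.09 and cathepsin S, Ctss, at -0.93. Of 14 neutrophil genes, 2 were lower when adjusted over the list alone, Csf3r (-0.88) and Cxcr2 (-1.73), while Clec4d (-0.74) and Il1r2 (-1.59) did not pass (camera adjusted p = 0.00791, and adjusted p = 0.47 with an estimated correlation). The Il1r2 log2 fold change was -3.33 without Prdx1 C52S 1. The neutrophil median of -0.53 was -0.84 without Prdx1 C52S 1. The call was lost without Prdx1 C52S 4 (median -0.25, camera adjusted p = 0.25) and without WT 6 (median -0.16, camera adjusted p = 0.056). None of 12 dendritic cell genes passed when adjusted over the list alone, although camera called the list (adjusted p = 0.0164, and adjusted p = 0.43 with an estimated correlation). Xcr1 was at -1.17, Fscn1 at -0.54, Flt3 at -1.05 and Itgae at -1.36, and this call was lost without WT 6 (camera adjusted p = 0.062). The dendritic cell median of -0.56 was -0.33 without WT 8, with Xcr1 at -0.64, Fscn1 at -0.32 and Itgae at -0.70. B and plasma cell genes were not called (0 of 20 when adjusted over the list alone, camera adjusted p = 0.36), with Ighm at 0.82 and Cd22 at -0.62.

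Matrix and biliary transcripts were lower in the Prdx1 C52S livers. Of 48 fibrosis and extracellular matrix genes, 31 were lower when adjusted over the list alone and 1 was higher, Col5a3 (0.84, named after its value was seen). The list had a median of -0.82 (camera adjusted p = 4.89e-09, and adjusted p = 0.42 with an estimated correlation), and 21 genes were lower on that scale without WT 8. The collagen chaperone Serpinh1 was at 9.45 ± 1.59 against 31.6 ± 14.7 FPKM (log2 fold change -1.40), the basement membrane collagen Col4a1 at 8.13 ± 0.6 against 22.1 ± 9.53 (-1.11), Vim at -0.76 and Col6a3 at -1.60. Of the genes named in advance, Col1a1 was at 5.05 ± 1.61 against 12.5 ± 4.76 (-1.02, SE 0.34, edgeR adjusted p = 0.13; -0.64 without WT 6) and Timp1 at 2.83 ± 0.897 against 5.76 ± 1.14 (-0.72, SE 0.27, edgeR adjusted p = 0.148). Acta2, a marker of contractile myofibroblasts, was at 2.02 ± 0.651 against 1.88 ± 0.478 (0.35, SE 0.34, edgeR adjusted p = 0.551), and its log2 fold change ran from 0.07 without Prdx1 C52S 4 to 0.58 without WT 9. Of 19 genes responsive to YAP and TGF-beta, 11 were lower when adjusted over the list alone (camera adjusted p = 1.31e-05, and adjusted p = 0.42 with an estimated correlation), with Tead1 at -0.84, Ltbp1 at -0.77, Ajuba at -1.39 and Ankrd1 at -3.87. Without WT 8, Ajuba was at -0.81 and Ankrd1 at -1.93, and 6 genes were lower when adjusted over the list alone. The YAP list median of -0.46 was -0.71 without Prdx1 C52S 1 and -0.73 without WT 9.

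All 18 cholangiocyte genes had negative fold changes, with a median of -2.81 that was -1.50 without WT 8, and 16 were lower when adjusted over the list alone (camera adjusted p = 7.91e-08, and adjusted p = 0.43 with an estimated correlation). Spp1 was at 83 ± 36.8 against 433 ± 270 FPKM, St14 at -2.97, Anxa13 at -2.57 and Ehf at -3.29 on the log2 scale. Without WT 8 the log2 fold changes were -1.93 for St14, -1.43 for Anxa13 and -1.87 for Ehf. Keratin 19 (Krt19), a marker of bile duct cells, was at 30.9 in WT 8, 3.97 in WT 6 and 2.09 in WT 9, and between 0.507 and 1.59 in the Prdx1 C52S libraries. Cell cycle genes had 39 of 40 negative fold changes with a median of -0.67, and none passed when adjusted over the list alone (camera adjusted p = 1.01e-07, and adjusted p = 0.45 with an estimated correlation). Kif11 was at -0.97, Bub1 at -1.38, Top2a at -0.90 and Foxm1 at -1.09. The cell cycle median was -0.48 without WT 8. Its median deviation was -0.19, -0.84 and -0.01 in Prdx1 C52S 1, 2 and 4. In WT 6, 8 and 9 the deviation was 0.25, 0.63 and 0.2. Stellate cell genes were not called (camera adjusted p = 0.365) and went both ways, with 3 of 18 higher and 3 lower when adjusted over the list alone, among them Pdgfra at -1.49 (-0.95 without WT 8) and Pth1r at 0.61. The other 4 were Pdgfrb and Hand2, which were lower, and Ngfr and Ecm1, which were higher, all named after their values were seen. Without WT 8, 6 stellate cell genes were higher and Pdgfra, Pdgfrb and Hand2 lower on that scale. Sinusoidal endothelial genes were not called (0 of 21 when adjusted over the list alone, camera adjusted p = 0.922), with Ramp2 at -0.82 and Stab1 at -0.44. Without WT 8, Stab1 and Fcgr2b, the latter named after its value was seen, were lower on that scale, and the median was -0.08 in place of 0.09.

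Genes of detoxification and of the thiol redox system were higher in the Prdx1 C52S livers. Of 35 targets of NRF2, a transcription factor that responds to oxidants, 32 had positive fold changes and 21 were higher when adjusted over the list alone, while 1 was lower, Akr1b8 (-0.89, named after its value was seen). The median was 0.63 (camera adjusted p = 2.89e-11, and adjusted p = 0.42 with an estimated correlation). Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, was at 103 ± 12.9 against 39.5 ± 6.14 FPKM (log2 fold change 1.65, SE 0.23). Gstm4, a glutathione transferase, was at 51.2 ± 2.51 against 27.4 ± 4.01 (1.17), the carboxylesterase Ces1g at 109 ± 9.49 against 62.3 ± 2.9 (1.08) and malic enzyme, Me1, at 116 ± 8.83 against 52.6 ± 9.57 (1.40). Of 19 genes of the peroxiredoxin and thioredoxin system, 7 were higher and 2 were lower when adjusted over the list alone (camera adjusted p = 0.000445, and adjusted p = 0.43 with an estimated correlation). The median of this system was 0.28, beside 0.34 for general hepatocyte genes. Whether this system, the NRF2 targets or the drug metabolism genes rose beyond hepatocyte genes in general was not tested. Sulfiredoxin, Srxn1, which repairs overoxidised peroxiredoxins, was at 41.5 ± 5.66 against 23.7 ± 5.4 (1.09), Txnrd1 at 0.74 and Txnrd3 at 0.66. The lower genes were Txnip, an inhibitor of thioredoxin, at 20.5 ± 1.5 against 58.1 ± 22.8 (-1.19), and Sesn1 (-0.55, named after its value was seen), and neither was lower on that scale without WT 8. The list of other antioxidant enzymes was not called (camera adjusted p = 0.0653), with 4 of 20 genes higher and 3 lower when adjusted over the list alone. Gpx3 was at -1.64 and glutathione reductase, Gsr, at 0.68. Named after their values were seen, Cat, Msrb2 and Sod1 were the other higher genes, and Gpx7 and Gpx8 the other lower ones. Camera called this list higher without WT 8 (median 0.20, camera adjusted p = 0.0232, and adjusted p = 0.31 with an estimated correlation), with 8 genes higher and 3 lower on that scale, Gpx3, Gpx7 and Aifm2. It was also called without Prdx1 C52S 2 (camera adjusted p = 0.027), WT 6 (0.037) or WT 9 (0.04).

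Stress-responsive groups went in different directions. Of 30 genes of the unfolded protein and integrated stress response, 4 were higher when adjusted over the list alone, the transcription factors Atf4 (0.67) and Atf5 (0.70), Dnajb9 (0.66) and Vldlr (1.12). Camera called this list higher (adjusted p = 0.00282, and adjusted p = 0.45 with an estimated correlation), with a median of 0.19 that was -0.05 after quantile normalisation, where the call was lost. This median was 0.09 without Prdx1 C52S 4, 0.11 without WT 6 and 0.32 without WT 9, and 7 genes were higher and 1 lower, Atf3, on that scale without WT 8. Of 30 acute phase genes, 6 were lower when adjusted over the list alone and 1 was higher, Il1rap (0.77, named after its value was seen; camera adjusted p = 0.0061, and adjusted p = 0.57 with an estimated correlation). The metallothionein genes had the largest differences of this list, with Mt2 at 13.6 ± 0.311 against 193 ± 131 FPKM (-3.53, SE 0.61) and Mt1 at 13.9 ± 1.52 against 156 ± 107 (-3.21, SE 0.60). Socs3 was at -1.54 and Steap4 at -1.28. Of 25 immediate early and heat shock genes, which are also a check of tissue handling, 4 were lower and 1 was higher when adjusted over the list alone (camera adjusted p = 0.00636, and adjusted p = 0.52 with an estimated correlation). Junb was at -0.87, Egr1 at -1.76, Btg2 at -1.04 and Ier3, named after its value was seen, at -1.65, and the higher gene was Klf2 (0.56), while without WT 8 only Junb was lower on that scale and none was higher. Without WT 9 both the acute phase call (median -0.14, camera adjusted p = 0.29) and the immediate early call (median -0.19, camera adjusted p = 0.13) were lost. Targets of p53 were not called (0 of 24 when adjusted over the list alone, camera adjusted p = 0.0835), with Gadd45b at -1.93 and Phlda3 at -1.20, but camera called them lower without WT 8 (median -0.22, camera adjusted p = 0.0212, and adjusted p = 0.33 with an estimated correlation). Ferroptosis and iron genes were not called (0 of 23, camera adjusted p = 0.345), with Acsl4 at -0.58 and Alox12 at -3 (-1.94 without WT 8), and their median of 0.14 and mean of -0.20 differed in sign. Without WT 8 the camera direction was lower (adjusted p = 0.868), and when adjusted over the list alone Acsl4, Alox12, Ptgs2, Slc39a14 and Cp were lower and Tfrc and Steap3 higher, all but the first pair named after their values were seen.

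Lipid synthesis genes were higher in the Prdx1 C52S livers. Of 25 genes of fatty acid and triglyceride synthesis, 13 were higher when adjusted over the list alone and none was lower, with a median log2 fold change of 0.81 (camera adjusted p = 2.67e-09, and adjusted p = 0.42 with an estimated correlation). Fatty acid synthase, Fasn, was at 158 ± 38.8 against 69.7 ± 6.64 FPKM (1.47, SE 0.21), and ATP citrate lyase, Acly, at 94.1 ± 26.1 against 42.1 ± 5.02 (1.46, SE 0.21). Pnpla3 and Me1 were the other members with the smallest p. Of 25 genes of cholesterol synthesis and uptake, 11 were higher when adjusted over the list alone (camera adjusted p = 9.41e-07, and adjusted p = 0.43 with an estimated correlation), among them Sc5d (1.09), Insig1 (1.36) and Acat2 (0.61). Bile acid and sterol transport had 11 of 28 genes higher on the same scale (camera adjusted p = 7.05e-07, and adjusted p = 0.42 with an estimated correlation). Abcg8, which with Abcg5 exports sterols into bile, was at 56.9 ± 2.45 against 28 ± 10.7 (1.34), Klb at 1.14, Abcc3 at 0.84 and Nr0b2, a nuclear receptor that represses bile acid synthesis, at 1.48. Fatty acid oxidation and PPAR-alpha targets had 35 of 40 positive fold changes, and none passed when adjusted over the list alone (camera adjusted p = 1.01e-07, and adjusted p = 0.49 with an estimated correlation), with Ehhadh at 0.70, Acaa1b at 0.88 and Acadm at 0.53. Without WT 8, 17 of these genes were higher and 3 lower, Angptl4, Acot1 and Acot2, when adjusted over the list alone, named after their values were seen. With mean biliary expression as a covariate the list median was -0.04 and the call was lost (camera adjusted p = 0.25). Biliary expression was itself lower in the Prdx1 C52S libraries, so this covariate also takes out part of the genotype difference. Lipid droplet and uptake genes were not called (camera adjusted p = 0.345), with 4 of 24 lower and 1 higher when adjusted over the list alone. The lower genes were Fabp4 (-0.88), Slc27a1 (-1.53), Lpl (-0.54) and Pnpla2, the lipase ATGL, named after its value was seen, and Vldlr was the higher one. Without WT 8 the camera direction was lower (adjusted p = 0.713), with 7 genes lower and 4 higher on that scale, Vldlr, Fitm1, Cideb and Cidea, the last 3 named after their values were seen.

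Genes of drug metabolism and of the pericentral zone were higher. Of 62 cytochrome P450 and drug metabolism genes, 21 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 3.81e-10, and adjusted p = 0.42 with an estimated correlation). Cyp2a5 was at 497 ± 79.8 against 142 ± 42.1 FPKM (2.11, SE 0.25), Ugt2b35 at 80.6 ± 5.92 against 32 ± 2.85 (1.61), Ugt2b5 at 1.15 and Ugt2b38 at 1.11. The lower genes were Fmo2 (-1.91) and Por (-0.90, named after its value was seen). All 22 pericentral hepatocyte genes had positive fold changes, and 11 were higher when adjusted over the list alone (camera adjusted p = 1.06e-09, and adjusted p = 0.42 with an estimated correlation). The median was 1 with all libraries and 0.67 without WT 8 (17 genes higher on that scale), in which this list was lower than in the other WT libraries. Cyp2c29 was at 282 ± 50.3 against 65.9 ± 28.5 (2.35), Cyp2c50 at 2.5, Cyp2c37 at 2.98 and Lgr5 at 1.01. Periportal genes were not called (0 of 21 when adjusted over the list alone, camera adjusted p = 0.39), with Tat at 0.79 and Sds at -0.45. Without WT 8, Tat, Cyp2f2, Pigr and Gls2 were higher and Sds, Cps1 and Ctsc lower on that scale, all but Tat and Sds named after their values were seen. Near-identical copies in the Cyp2a, Cyp2c, Ugt2b and Gstm families share sequence, so that the values of single members are uncertain.

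Transcripts of energy and amino acid metabolism were higher, with list medians between 0.34 and 0.53. The general hepatocyte list had a median of 0.34 as well, and of 0.20 without WT 8. Whether these groups rose beyond hepatocyte genes in general was not tested. All 68 nuclear-encoded respiratory chain genes had positive fold changes with a median of 0.34, and none passed when adjusted over the list alone (camera adjusted p = 2.45e-17, and adjusted p = 0.43 with an estimated correlation). Without WT 8 the median was 0.25 and 35 genes were higher when adjusted over the list alone. Ndufa10 was at 35 ± 1.44 against 30 ± 1.26 FPKM (0.50), Sdhb at 0.54, Ndufa11 at 0.37 and Sdhd at 0.50. Of 13 mitochondrially encoded transcripts, 7 were higher when adjusted over the list alone (camera adjusted p = 0.000445, and adjusted p = 0.51 with an estimated correlation), with mt-Nd6 at 0.58, mt-Atp8 at 0.55, mt-Atp6 at 0.59 and mt-Nd4l at 0.52, and 12 were higher on that scale without WT 8. This list and that of cytosolic ribosomal proteins were set in advance as checks of RNA quality and handling. Mitochondrial genes held 6.63%, 6.56% and 6.6% of the counts in Prdx1 C52S 1, 2 and 4. In WT 6, 8 and 9 they held 5.55%, 5.42% and 6%. Whether RNA quality or handling differed between the groups was not tested. Amino acid and urea cycle genes had 14 of 38 higher and 1 lower, Sds, when adjusted over the list alone (camera adjusted p = 7.29e-06, and adjusted p = 0.42 with an estimated correlation), with Gnmt at 0.86, Cbs at 0.74, Kynu at 0.84 and Tat at 0.79. Gluconeogenesis and glycolysis genes had 5 of 25 higher when adjusted over the list alone (camera adjusted p = 2.56e-06, and adjusted p = 0.43 with an estimated correlation), the glucokinase regulator Gckr (0.87), Irs1 (1), Pygl (0.94), Ppp1r3c (1.85) and Ppp1r3b (1.08), the last named after its value was seen. Without WT 8, 9 genes of this list were higher on that scale.

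General hepatocyte genes had a median log2 fold change of 0.34, and none of 27 passed when adjusted over the list alone (camera adjusted p = 0.00305, and adjusted p = 0.51 with an estimated correlation). Foxa3 was at -0.65, Tat at 0.79 and Apoh at 0.64, and the median was 0.20 without WT 8 and -0.04 after quantile normalisation. Without WT 8, 9 genes were higher and 2 lower on that scale, Foxa3 and Cps1. Male-biased liver genes were called higher (camera adjusted p = 0.000209, and adjusted p = 0.51 with an estimated correlation), with 2 of 25 higher, Ugt2b38 (1.11) and Elovl3 (2.65), and 1 lower, Selenbp2 (-2.10), when adjusted over the list alone. Mup21 was at 1.40 (2.26 without WT 6) and did not pass. Among the WT libraries their median deviation was -1.37 in WT 8, -0.91 in WT 9 and 0.87 in WT 6, and the median log2 fold change of 1.05 was 2 without WT 6. Without WT 8 only Ugt2b38 passed on that scale, and with the biliary covariate the median was -0.70 and the call was lost (camera adjusted p = 0.49). Female-biased genes were not called (1 of 23 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.14), with Gstt3 at 1.31 and Fmo2 at -1.91, and none passed on that scale without WT 8. Camera called them higher without Prdx1 C52S 2 (camera adjusted p = 0.046), Prdx1 C52S 4 (0.011) or WT 9 (0.011). Erythroid genes were called higher (camera adjusted p = 0.000508, and adjusted p = 0.43 with an estimated correlation), with 4 of 9 higher when adjusted over the list alone, Hba-a1 (2.03), Hba-a2 (2.07), Hbb-bs (2.20) and Hbb-bt (2.20). These globin transcripts were highest in Prdx1 C52S 1 and 2, and without WT 8 0 of the 9 genes passed on that scale. Cytosolic ribosomal protein genes were called lower with a median of -0.09 (camera adjusted p = 0.00982, and adjusted p = 0.72 with an estimated correlation), and 0 of 74 passed when adjusted over the list alone. Rps15a was at -0.27, Rps12 at -0.26, Rps21 at -0.21 and Rpl21 at 0.37, and this call was lost without Prdx1 C52S 1 (camera adjusted p = 0.25), Prdx1 C52S 2 (0.078) or WT 9 (0.067). Clock genes were not called (0 of 22, camera adjusted p = 0.927), with Nr1d1 at 1.02 and Tsc22d3 at 0.75, of which Tsc22d3 was higher when adjusted over the list alone without WT 8. Adipose tissue genes were not called (camera adjusted p = 0.738), with 2 of 7 higher, Car3 (1.71) and Cfd, and 1 lower, Fabp4 (-0.88), when adjusted over the list alone; their median of -0.24 and mean of 0.39 differed in sign. Without WT 8, Car3 was higher and Fabp4 and Cidec, the latter named after its value was seen, were lower. Pancreas and muscle genes had too few members above the filter to be tested (2 and 4).

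**Figure D3:**
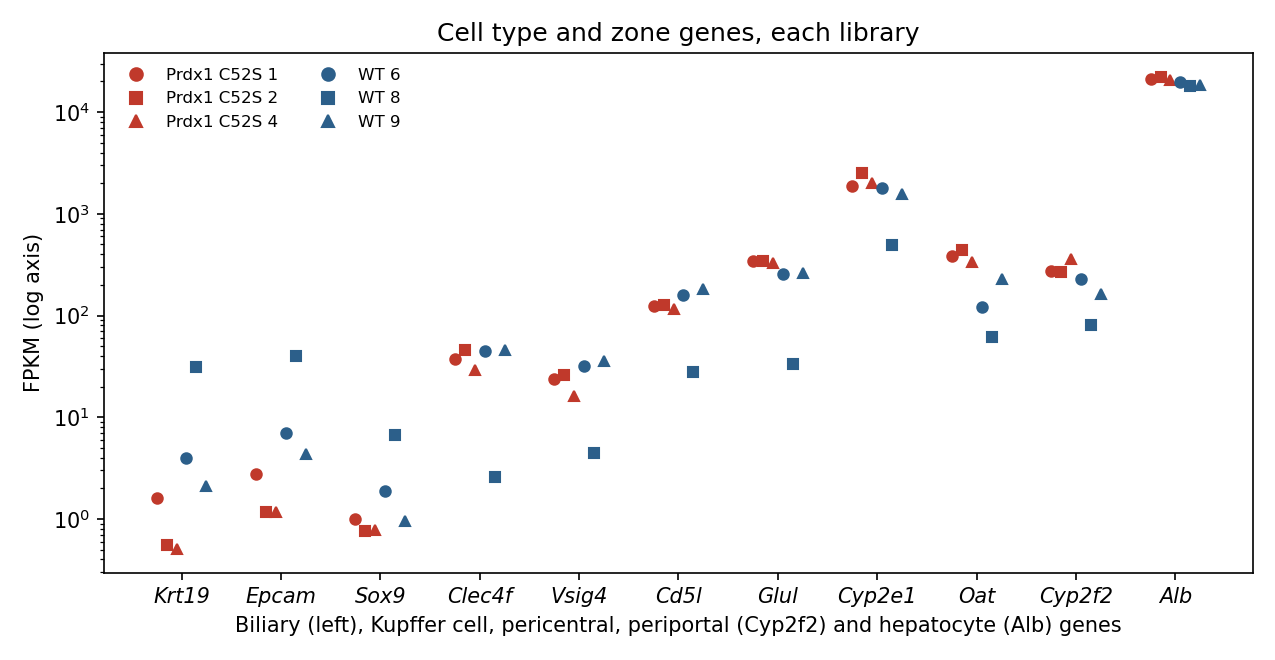
FPKM on a log axis (vertical) of genes of biliary cells, Kupffer cells, pericentral hepatocytes, periportal hepatocytes and all hepatocytes (horizontal), with 1 point per library (red, Prdx1 C52S; blue, WT). WT 8 has the highest Krt19 (30.9) and the lowest Clec4f (2.56) and Glul (33.3), while albumin, Alb, lies between 18100 and 22300 in the 6 libraries.

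The directional fry test called 5 lists, each of them lower, namely chemokine and cytokine receptors, the Toll-like receptor and NF-kB pathway, chemokines and cytokines, monocytes and MHC class II presentation. The 2 groups did not overlap in 6602 of 18931 genes (34.9%), where the mean over all equal splits of the libraries is 10%. Genes vary together, so a single split can lie far from that mean, and this share does not exclude chance. Scaling by library totals alone in place of TMM moved the median log2 fold change of all genes from -0.03 to -0.34, so that directions given here are relative to the bulk of the transcripts. With mean biliary expression as a covariate, the calls of pericentral hepatocytes (median 0.09), gluconeogenesis (-0.02), YAP and TGF-beta responsive genes, peroxiredoxins, mitochondrial transcripts, erythroid cells, the unfolded protein response, hepatocytes, cholangiocytes and dendritic cells were lost as well. The cholangiocyte list behind this covariate had median deviations of -0.43, -1.35 and -1.62 in Prdx1 C52S 1, 2 and 4. In WT 6, 8 and 9 they were 0.6, 2.76 and 0.04. The covariate thus follows genotype, and the lost calls do not tell biliary content from genotype. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries only.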

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

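Scaling by library totals only, counts divided by 4, DESeq2 without WT 8, the biliary covariate, and camera with an estimated correlation or fry without WT 8 were chosen after seeing the data. The counts of single genes depended on the test and on WT 8. Against 0 higher and 0 lower in edgeR, DESeq2 gave 1145 and 1698, voom with library quality weights 1023 and 1006, limma on log2(FPKM + 1) 55 and 194, limma on log2(FPKM + 0.1) 90 and 307, quantile normalisation 8 and 11, no filter 105 and 91, a mean CPM of at least 1 46 and 42, library totals only 35 and 125, counts divided by 4 43 and 40, and DESeq2 without WT 8 1289 and 1157. DESeq2 size factors, no robust estimation and the biliary covariate gave 0 and 0. Leaving out 1 library gave 0 to 522 higher and 0 to 375 lower, with 522 and 375 without WT 8, 63 and 69 without WT 9 and 0 and 0 for each of the other 4. Of the 2843 genes called by DESeq2 and the 2029 called by voom, 823 and 819 were among the 897 called by edgeR without WT 8. The share of higher genes among the calls was 40.3% with DESeq2, 50.4% with voom, 58.2% without WT 8, and 21.9% to 22.7% with library totals or FPKM, which apply no TMM factor. The smallest adjusted p was 0.0553 with all 6 libraries in edgeR and 0.0146 with no filter, and the cause of the differences was not tested.

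The number of lists called by camera was between 31 and 38 under the other settings of normalisation, filter, weights and left-out library, and was 0 with an estimated correlation, also without WT 8. With the biliary covariate 29 lists were called, of which 23 were among the 35 in the same direction, and 1437 genes had an unadjusted p under 0.05 against 4983. Directional fry called 5 lists, and 22 without WT 8, of which 20 were among the 35 lists, in the same direction, and mixed fry 36. Of the 35 lists, 16 were called in the same direction under every setting other than these set tests. Lists have no value for DESeq2 and for fits without robust estimation. Of 186 named genes and list genes, 178 kept their direction in every setting. Prdx1 reversed with quantile normalisation (-0.16), library totals only (-0.01) and the biliary covariate (-0.04). The Clec4f log2 fold change reversed with DESeq2 without WT 8 (-0.09) and the covariate (-1.89), and ranged from -0.08 to 0.87 over the left-out libraries, and Il1b from -0.70 to 0.07. With the covariate, Ccl2 (0.38), Acta2 (-0.48), Xcr1 (0.15), Fscn1 (0.07) and Itgae (0.05) reversed, as did the list medians of fatty acid oxidation (-0.04), male-biased genes (-0.70), hepatocytes (-0.07) and, by construction, the camera direction of cholangiocytes (-0.02). Gluconeogenesis had a median of -0.02 there and lost its call. The hepatocyte list reversed with quantile normalisation too (-0.04). The causes of these reversals were not tested. Because the biliary covariate was itself lower in the Prdx1 C52S libraries, its reversals and lost calls cannot be credited to biliary content. No paired analysis was possible because the groups share no replicate number. At about 4 counts per fragment, genes near 0.1 FPKM, such as Cd3e or Vcan, rest on few fragments, and their fold changes are the least certain.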

Other observations

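The tests on WT 8, on the macrophage genes and on the hepatocyte share, and the counts of splits for the single genes, were chosen after the results were seen, as were the KEGG pathways. KEGG pathways annotated in the table gave further groups. Of 293 pathways, camera called 117, 53 higher and 64 lower, and 0 with an estimated correlation, and 109 were called in the same direction without WT 8. Branched-chain amino acid degradation (51 genes, median log2 fold change 0.54, adjusted p = 2.66e-12, and adjusted p = 0.52 with an estimated correlation) stood first. The proteasome (44 genes, median 0.38, adjusted p = 4.61e-10, and adjusted p = 0.52 with an estimated correlation) and the peroxisome (82 genes, median 0.45, adjusted p = 2.68e-09, and adjusted p = 0.52 with an estimated correlation) were higher as well. Hematopoietic cell lineage (79 genes, median -0.69, adjusted p = 2.4e-06, and adjusted p = 0.52 with an estimated correlation) and ECM-receptor interaction (71 genes, median -0.72, adjusted p = 6.18e-06, and adjusted p = 0.52 with an estimated correlation) were lower.

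The edgeR test without WT 8 called 897 genes, and the following were picked after their values were seen, from the 12 largest fold changes in each direction among 760 genes with non-overlapping groups and at least 1 FPKM in the higher group. Beside Pnpla3, its relative Pnpla5 was higher (log2 fold change 2.39, adjusted p = 0.0419), as were Lrtm1 (3.17, adjusted p = 0.00566), the sterol 12-alpha-hydroxylase Cyp8b1 (1.56, adjusted p = 0.0442), the succinate receptor Sucnr1 (1.61, adjusted p = 0.0131), the water channel Aqp4 (1.79, adjusted p = 0.0134), and Tbx3os1 (1.95, adjusted p = 0.0209). Lower genes were the matrix metalloproteinase Mmp7 (-3.84, adjusted p = 0.0254), the translation repressor Eif4ebp3 (-3.80, adjusted p = 0.0369), the glucocorticoid-responsive Fkbp5 (-1.94, adjusted p = 0.00566), Enho (-2.07, adjusted p = 0.0208), the immunoglobulin gene Igha (-2.14, adjusted p = 0.0251) and Chd9 (-1.83, adjusted p = 0.0264). With all 6 libraries their log2 fold changes had the same signs and adjusted p-values from 0.0553 to 0.107. Metallothioneins stayed low in all 3 Prdx1 C52S libraries (Mt1 13.9 ± 1.52 FPKM), while the WT values were far apart (156 ± 107).

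WT 8 stood apart from WT 6 and 9 by more biliary transcripts (median log2 difference 2.36 over 18 genes) and fewer Kupffer cell (-2.74 over 12 genes) and pericentral ones (-1.37 over 22 genes). Admixture of bile duct or other tissue would lower all hepatocyte genes alike, but the pericentral list lay 1.27 below the periportal one (difference -1.27, 95% bootstrap interval over genes -1.97 to -0.64), which argues against dilution as the whole cause. An earlier test of dilution, Kupffer minus hepatocyte genes, had decided nothing (difference -2.25, interval -2.94 to -0.42, against a bound of -1), and the zonal comparison was chosen after that outcome. A shallow library is argued against by its 25371 genes above 0, the most of all 6 libraries, at 74725684 counts. These values speak to depth only. Other faults of the library were not tested, and its mean correlation with the other libraries was the lowest (0.937). A liver with more advanced ductular reaction and loss of resident Kupffer cells may be one biological explanation that stays open, as does an effect of the sampled region, and neither was tested.

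Lower macrophage transcripts were set against 3 technical explanations. A smaller share of all non-parenchymal cells would lower sinusoidal endothelial genes as well, but their median lay 0.73 above that of macrophage genes (95% interval over genes, which are not independent, 0.36 to 0.95). WT 8 alone does not carry the pattern, since the macrophage median without it was -0.76 (-0.89 to -0.65). Erythroid genes gave no sign of more blood in the WT livers, since their median was 1.99 (0.54 to 2.20), higher in Prdx1 C52S. That interval is over genes and does not measure the spread between libraries. Their median deviation was 1.25, 1.75 and -0.15 in Prdx1 C52S 1, 2 and 4, and -0.8, -1.15 and -0.27 in WT 6, 8 and 9. A smaller number of recruited macrophages in the Prdx1 C52S livers or lower expression per cell may underlie the lower macrophage transcripts, which bulk RNA does not separate. A difference between these few libraries unrelated to genotype stays open.

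Higher fat synthesis transcripts were weighed in the same way. A larger share of hepatocytes would raise them as much as general hepatocyte genes, but without WT 8 their median lay 0.35 above that of the hepatocyte list (95% interval 0.09 to 0.77). The lower limit lies under the bound of 0.1 set for this test, so a larger hepatocyte share stays open as a part of the pattern. Whether the WT mice were more fasted at collection could not be decided. Over 12 fasting-induced genes, a test written before their values were seen, the median log2 fold change was 0.04 (-0.23 to 0.72), with members on both sides, such as G6pc at 1.35 and Lpin1 at -1.10. Unlike the hepatocyte comparison, this test used all libraries. Without WT 8, G6pc was at 1.11 and Lpin1 at -1.54. Feeding state and an effect of the allele both stay open.

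A hypothesis that passenger alleles flanking the mutated locus change nearby genes was tested, as written before the values were seen, on the 220 tested genes within 10 Mb of Prdx1. Of these, 20% had an unadjusted p under 0.05, against 26.4% of all other genes (Fisher's exact test, two-sided, p = 0.031), so no excess near the locus was seen. Single passenger effects are not excluded by this.

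The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes higher and for genes lower past adjusted p 0.05, all 10 splits gave at least the real 0, and the highest other value was 0. A real value of 0 fixes this outcome in advance, so the comparison decides nothing for them. For genes at an unadjusted p under 0.05, 1 split, the real one, reached 4983, and the highest of the others was 1149. For gene lists called by camera, 1 split, the real one, reached 35, but the highest of the others was 33 and the lowest 14. Each of the other splits still holds more libraries of one genotype on each side, so these counts do not separate the genotype from other variation between libraries.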
